A study of Mus musculus with 16 samples.

How the data were processed

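Chromatin immunoprecipitation and sequencing (ChIP-seq), which recovers and counts the DNA bound by a chosen protein, was run by the submitters on ventricles of mouse hearts. The series holds 16 samples. Of these, 8 are immunoprecipitated libraries with a peak list each, and 8 are inputs of sheared chromatin, which are not analysed here. By the style of their titles the samples form 2 sets, one with Meis1 and one with Hoxb13, each with its own inputs. A difference between the antibodies therefore cannot be told apart from a difference between the sets. Each antibody, one raised against Meis1/2 and one against Hoxb13, has 2 libraries from vehicle-treated and 2 from drug-treated mice. The labels describe ventricles of 2 hearts as biological duplicates for each sample, which can mean a pool of 2 hearts per library or 1 heart per replicate; every p-value over libraries therefore measures the spread between these libraries only.

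Reads were processed by the submitters with FastQC 0.11.5, Bowtie2, Picard 1.127, MACS2 and HOMER on the mouse build mm10, per the submitters' processing notes. The options of the peak caller, the input that served as its control and any filter are not given in the sources used here. The deposited lists are in the broadPeak layout without a header and hold 1 list per library, so replicates were not pooled before calling. The fold enrichment of each peak over its local background is the deposited ratio, averaged by the caller over the peak. The deposited −log10 p and −log10 q values belong to the same peaks, and the smallest −log10 q in any list is 1.00, a q of 0.1. The deposited score of each peak equals 10 times its −log10 q, rounded down, in 100% of the peaks, and was not used further. Folds and q-values are the authors' own values and ranked peaks only within their own list. Sequencing depth is unknown, so no detection limit could be attached to an absent peak, and a peak number can move with depth as well as with binding.

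Groups were taken from the labels. The names of the deposited second-replicate Meis1 lists carry the letter used for the other group, so the labels and the file naming disagree about which of these lists is control; the labels were followed. Group-specific regions and replicate overlap were also computed for the other ways of splitting the 4 libraries of an antibody into pairs, which include the exchanged assignment, and the Meis1 peak number, covered length, gene-end share and overlap with Hoxb13 for the exchanged assignment. Calls in Paro/Neo by quartile of control fold and the test of metabolism genes were computed for the labels alone.

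Chromosomes 1 to 19, X and Y were analysed. Peaks of the 4 libraries of an antibody were merged into regions wherever they shared at least 1 bp, and a region was called in a library when it held a peak of that library. The numbers of peaks and the covered length were compared between groups on the log2 scale by an exact two-sided permutation test over the 6 orders of 4 libraries, whose smallest possible p is 0.333; the difference between the antibodies was tested over 36 orders, with a smallest p of 0.0556. Group-specific regions were those called in both libraries of a group and in neither of the other. Their ratio was computed after adding 0.5 to each count. Regions counted for 1 antibody come from the merge of its 4 libraries, while the overlap of the antibodies used the merge of the 2 libraries of a group, so regions called in both Hoxb13 libraries number 901 and 946 for control and 700 and 701 for Paro/Neo. Overlap between libraries was the Jaccard share, the shared regions divided by all merged regions of a pair. Chance overlap came from random placement within chromosomes (100 placements per pair of libraries and 1000 for Meis1 against Hoxb13), which leaves out mappability and the clustering of binding near genes, so it understates the overlap that 2 unrelated factors would share.

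Gene positions came from a RefSeq table of assembly GRCm38.p6, which has the coordinates of mm10, with 21883 protein-coding genes on these chromosomes. The table gives the start and end of each gene without strand, exons or sequence. The planned share of peaks at transcription start sites was therefore replaced by the share within 1 kb of either end of a protein-coding gene, gene lists used the gene body with 5 kb on both sides, exon and intron could not be assigned, and the planned motif counts were not run. The 20 gene lists with 428 entries, all matched to the table, were fixed before the data were examined, as were the tests, the groups and most alternatives. For each list, members holding a region called in 2 or more libraries of an antibody were counted against 10000 random lists matched on gene length in 10 classes, with one-sided permutation p-values adjusted by Benjamini-Hochberg over the 40 tests; the smallest unadjusted p is 0.0001. Genes are not independent replicates. Exact binomial (Clopper-Pearson) 95% intervals cover counting error only.

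Named regions followed a rule fixed in advance: up to 10 control-specific, 10 Paro/Neo-specific and 10 regions called in all 4 libraries of an antibody but not in all 8, ranked by mean percentile of fold within their own lists and named by a protein-coding gene that they overlap or that lies within 10 kb; up to 4 members of each list; and always Meis1, Meis2, Hoxb13, Cdkn1a, Cdkn2a, Cdkn2b, Rcan1 and Ppp3ca. Some regions that the rule selects are not reported here.

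The procedures were tested on simulated data. With randomly placed regions, 3 of 200 list tests were called for Meis1 and 1 of 200 for Hoxb13, and 20 of 20 planted lists (12 of 25 members given a region) were found for each antibody. Of 200 randomly placed Meis1 sets, 1 passed the overlap test, and 200 of 200 planted group-specific regions were recovered. These outcomes check the code only, since the sets came from the same placement as the chance overlap and the planted regions were identical intervals. Random regions were placed without clustering near genes, so the simulations do not show how often the tests pass wrongly for peaks clustered like these. Alternatives were stricter q-values, lists without the regions called in all 8 libraries, every sequence in the lists, joined peaks, a larger minimum overlap, equal list lengths, other windows, an unmatched test of the lists, each library left out and a replicate block. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.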

Results

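Meis1 and Hoxb13 are homeodomain transcription factors studied as regulators of the postnatal exit of cardiomyocytes from the cell cycle. Their binding was profiled by ChIP-seq in ventricles of mice at postnatal day 15. From postnatal day 7 the mice had received either vehicle (control) or the aminoglycoside antibiotics paromomycin and neomycin together (Paro/Neo) at 150 mg/kg, given 2 times a day by intraperitoneal injection for 7 days. The comparison asks whether the drug pair changed where each factor was bound. Peak lists of 2 control and 2 Paro/Neo libraries were used for each antibody. The Meis1 antibody is described as recognising Meis1/2, so its peaks may hold sites of Meis2 as well. Lists held 3529 and 3176 Meis1 peaks in the control libraries and 1541 and 1025 in the Paro/Neo libraries. Lists of Hoxb13 held 5202 and 1121 peaks in control replicates 1 and 2, and 821 and 16963 in Paro/Neo replicates 1 and 2. Median peak widths ran from 255 to 260 bp for Meis1 and from 348 to 495 bp for Hoxb13.

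**Figure D1:**
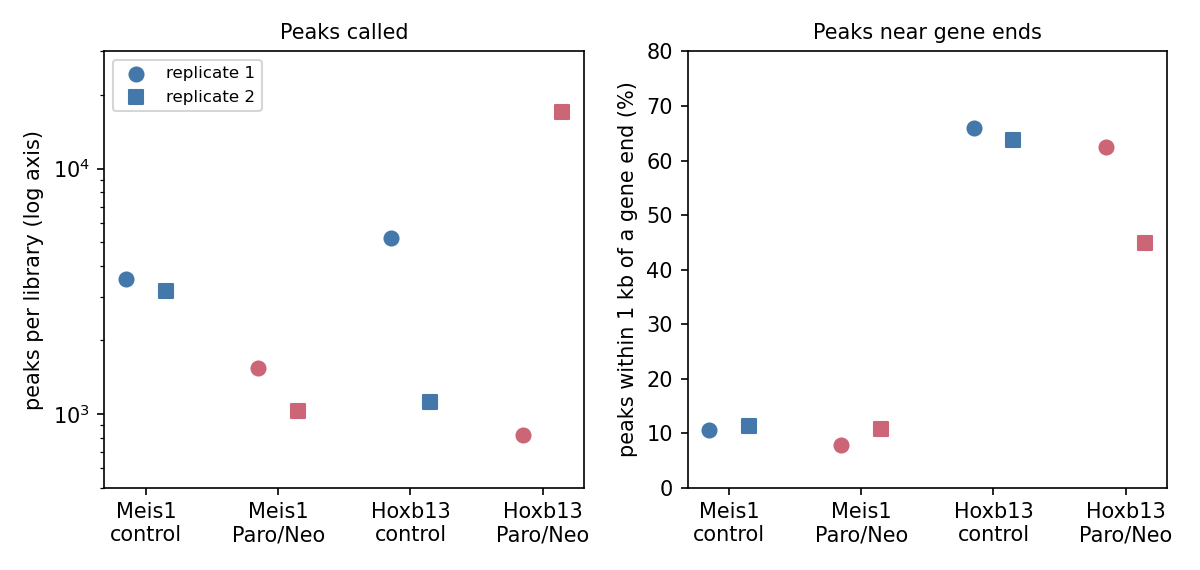
Peaks per library on a log axis (left) and the percentage of peaks within 1 kb of either end of a protein-coding gene (right) for each antibody and treatment; blue marks are control and red marks Paro/Neo libraries, circles replicate 1 and squares replicate 2. Both Meis1 Paro/Neo lists (1541 and 1025 peaks) lie below both Meis1 control lists, while the Hoxb13 replicates of each group lie far apart.

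Meis1 regions called in at least 2 libraries lay more often than in length-matched lists at genes of the contractile apparatus, of calcium handling and of its own protein family. Regions called in at least 2 Meis1 libraries lay at 9 of 26 sarcomere genes, where length-matched random lists held 1.95 on average (adjusted permutation p = 0.00067). Calcium handling and conduction genes held regions at 10 of 23 members against 3.07 in matched lists (adjusted permutation p = 0.0023). The TALE homeobox genes, the family of Meis1 and its partner proteins, held regions at 6 of 11 members against 1.41 (adjusted permutation p = 0.0027). At Myl2, which encodes the ventricular regulatory light chain of myosin, a region of 639 bp (chromosome 5, 122094249 to 122094887, within the gene) was called in all 4 libraries at a mean fold percentile of 99.7. The highest-ranked regions at Ldb3, Tnnt2 (cardiac troponin T) and Actn2 were called in 3 libraries each, while Tnnt2 held a peak in all 4. The 9 members include the neighbours Myh6 and Myh7, named after their values were seen, which share a single region (chromosome 14, 54966724 to 54966977) called in both control libraries. Further regions called in all 4 libraries with mean fold percentiles from 99.4 to 99.9 lay at Gse1, Bpifb1 and Dot1l, a histone methyltransferase gene, and outside Arl8a and Mmp13.

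Among the calcium handling genes, Cacna1c and Cacnb2, subunits of the L-type calcium channel, Hcn4, a pacemaker channel, and Jph2, which holds the junction between plasma membrane and sarcoplasmic reticulum, each carried a region in all 4 Meis1 libraries. The TALE members with a region in all 4 libraries included Pknox1 and Meis1 itself (chromosome 11, 19018517 to 19018821, percentile 57.7). Meis2 and Tgif2 had regions in 2 libraries. The TALE call rested on single libraries: without control replicate 1 it held 3 members (adjusted permutation p = 0.162) and without Paro/Neo replicate 1 it held 4 (adjusted permutation p = 0.0702). With regions called in all 4 libraries, 1 of the 20 lists, calcium handling and conduction, passed for Meis1. Sarcomere genes then held 1 member against 0.551 in matched lists (adjusted permutation p = 0.953). TALE homeobox genes held 3 against 0.408 (adjusted permutation p = 0.068).

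**Figure D2:**
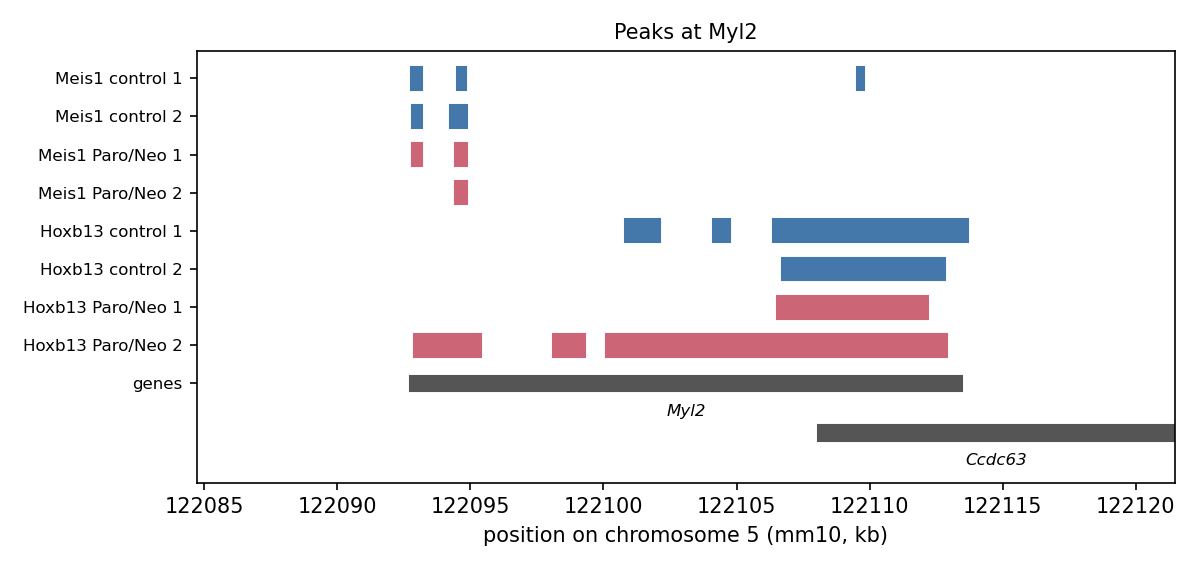
Map of the Myl2 locus on chromosome 5 (mm10, position in kb), with each peak of the 8 libraries as a bar, blue for control and red for Paro/Neo, and protein-coding genes in grey. A Meis1 peak lies between 122094249 and 122094887 in all 4 Meis1 libraries, while the widest Hoxb13 peak of each library, up to 12818 bp, lies towards the other end of the gene, where it overlaps Ccdc63; a Hoxb13 peak of 2536 bp in Paro/Neo replicate 2 covers the Meis1 region.

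The remaining lists did not pass for Meis1. Cardiac transcription factor genes held regions at 5 of 21 members (adjusted permutation p = 0.14), among them Prdm16, Myocd and Mef2a in all 4 libraries. The list of CDK inhibitors and pocket proteins, which restrain the cell cycle, held 1 of 10. Glycolysis and HIF genes held 4 of 24 (adjusted p = 0.088), fatty acid oxidation genes 4 of 22 (adjusted p = 0.12), and oxidative phosphorylation genes 1 of 32, by the same permutation test. The calcineurin and NFAT list held 3 of 10 members, the ErbB, IGF and insulin signalling list 4 of 18, and the Hippo pathway 2 of 18. Markers of other cardiac cell types held regions at 1 of 17 fibroblast, 2 of 19 endothelial, 1 of 10 smooth muscle and pericyte, 0 of 16 macrophage and leukocyte, and 0 of 8 erythroid genes; the regions at Pecam1, Tek, Gsn and Abcc9 were called in all 4 libraries. No region in at least 2 libraries lay at any of the 33 cell cycle drivers, 39 Hox genes or 41 ribosomal protein genes, and 1 lay at the 30 genes of other tissues. In all, 5 of the 20 lists had an unadjusted permutation p under 0.05 and 3 passed after adjustment.

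After Paro/Neo, Meis1 peaks were 2.66-fold fewer by the mean of the log2 numbers, with 1283 ± 365 peaks against 3353 ± 250 in control (SD, n = 2 each). The covered length was 398 ± 110 kb against 1040 ± 68.0 kb (SD, n = 2 each). Regions called in both control libraries and in neither Paro/Neo library numbered 807, against 15 for the reverse. The control-specific regions with the highest fold percentiles included those at Diaph2, Plekhh1, Hes6 (12 bp from the gene, chromosome 1, 91414050 to 91414401), Gnptab and Arhgef3, at mean percentiles from 84.4 to 92.2. The Paro/Neo-specific regions were weak within their lists, and the strongest had a mean percentile of 54.7. Those with a named gene included Ccdc28b (percentile 47.5) and Pxdn (43.9). Regions within Il31ra, Zc3h7a and Lars2 and 7.26 kb from Tra2a lay near the bottom of the lists, at percentiles from 2.30 to 2.79. The difference in peak number was −1.41 on the log2 scale, and all 4 libraries followed it, but 2 against 2 libraries cannot give a p under 0.333, the value obtained (exact two-sided permutation test). The same p was obtained for covered length (−1.41, exact permutation test).

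Regions with a high fold in the controls were called again more often than weak ones. Of the 2033 Meis1 regions called in both control libraries, 610 were called in both Paro/Neo libraries, 616 in 1 and 807 in none. In the weakest quartile of control fold rank, 71.1% of regions (95% exact interval 67.0 to 75.0) were absent from both Paro/Neo lists, and in the strongest quartile 4.33% (2.73 to 6.48). Sarcomere genes held a peak at 12 and 10 members in the control libraries and at 7 and 2 in the Paro/Neo libraries, where matched lists held 2.70, 2.58, 1.33 and 0.894. Fatty acid oxidation genes held 4 and 6 against 0 and 0, where matched lists held 1.89, 1.82, 0.906 and 0.627, so that 0 is close to the matched value. Glycolysis and HIF genes held 8 and 5 against 1 and 0, Hippo pathway genes 5 and 5 against 1 and 1, calcium handling genes 15 and 10 against 7 and 9, TALE homeobox genes 7 and 4 against 5 and 3, and endothelial markers 2 in each of the 4 libraries. Matched lists held 1.83, 1.77, 0.8625 and 0.59 for glycolysis and HIF, and 2.42, 2.30, 1.18 and 0.803 for the Hippo pathway. The Paro/Neo counts of both lists lay close to these values. For calcium handling, matched lists held 4.09, 3.94, 2.10 and 1.43. For TALE homeobox genes they held 1.90, 1.855, 1.01 and 0.6955, and for endothelial markers 2.23, 2.14, 1.07 and 0.7875. The differences between groups were not tested. The regions at Ppargc1a, a coactivator of mitochondrial biogenesis, and at Lpl, Ppara and Cd36, which serve fatty acid use, were called in both controls and in neither Paro/Neo library; this list did not pass for Meis1.

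**Figure D3:**
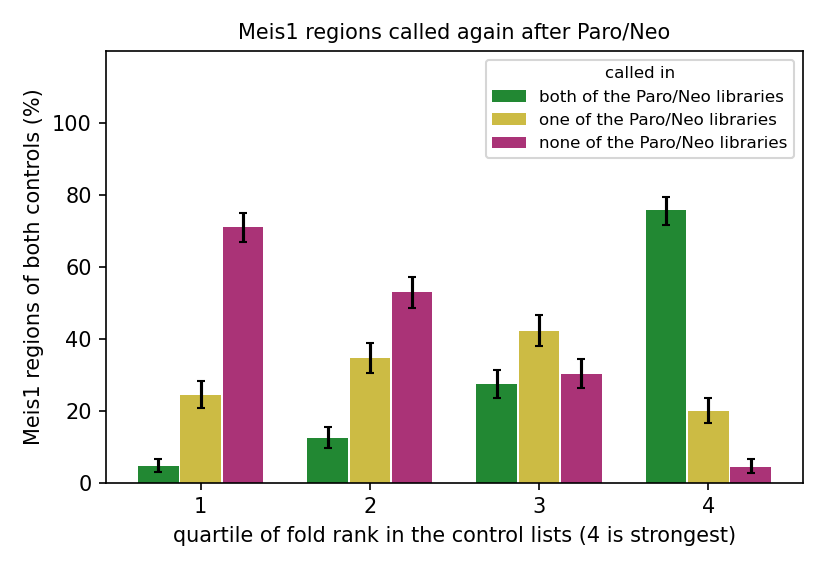
Percentage of the 2033 Meis1 regions of both control libraries that were called in both, 1 or none of the Paro/Neo libraries, by quartile of mean fold rank in the control lists; error bars are 95% exact binomial intervals. The share absent from both lists runs from 71.1% in the weakest quartile to 4.33% in the strongest.

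Libraries of a group shared more Meis1 regions than libraries of different groups when whole lists were compared. The Jaccard share was 0.435 between the controls, 0.340 between the Paro/Neo libraries and 0.273 ± 0.047 (SD of 4 pairs) between groups. The unequal list lengths limit the shares between groups, so this difference does not show that the groups differ in their sites. A single control list held from 74.6% to 80.8% of the peaks of a Paro/Neo list. Within groups, replicate 1 held 64.0% of the peaks of replicate 2 in control and 63.5% in Paro/Neo. With every list reduced to its strongest 1025 peaks, the share was 0.512 between the controls, 0.390 between the Paro/Neo libraries and 0.450 ± 0.048 (SD of 4 pairs) between groups, and control-specific and Paro/Neo-specific regions numbered 75 and 35. Pairs with Paro/Neo replicate 2 shared 0.390 to 0.410 and the other pairs 0.480 to 0.512. The lower shares thus followed that library, while Paro/Neo replicate 1 shared 0.480 and 0.501 with the controls. The 807 against 15 split belongs to the labels' grouping: exchanging the second replicates, as the file naming would have it, gave 34 regions specific to the pair of control replicate 1 and Paro/Neo replicate 2 against 82 for the other pair. With these replicates exchanged, the difference in log2 peak number was 0.22 and that in log2 covered length 0.22 (exact two-sided permutation p = 1 for both). Without Paro/Neo replicate 2 the counts were 978 against 265, and without Paro/Neo replicate 1 they were 1253 against 150. Without control replicate 1 they were 1819 against 28, and without control replicate 2 they were 2144 against 28.

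**Figure D4:**
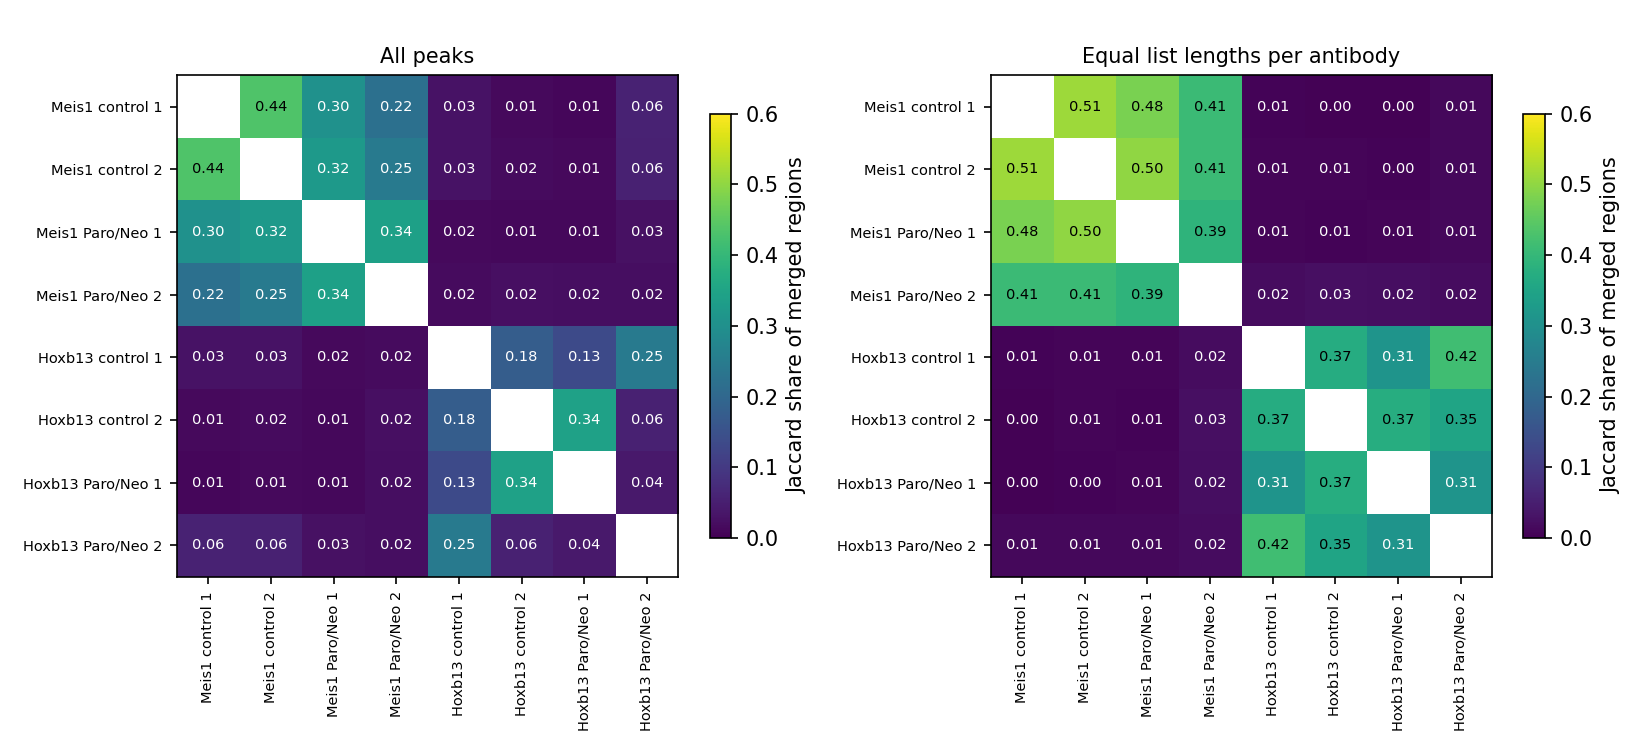
Jaccard share of merged regions for each pair of the 8 libraries with all peaks (left) and with equal list lengths within each antibody (right, 1025 Meis1 and 821 Hoxb13 peaks); colour and printed values run from 0 to 0.6. At equal list lengths Meis1 libraries of different groups share 0.450 on average, between the 0.512 of the controls and the 0.390 of the Paro/Neo libraries. Meis1 pairs with Paro/Neo replicate 2 share 0.390 to 0.410 and the other Meis1 pairs 0.480 to 0.512.

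The genes of both factors and a fixed set of cell cycle inhibitor and calcineurin genes were examined whatever their values. No Meis1 library had a peak within 5 kb of Cdkn1a, Cdkn2a or Cdkn2b, which encode inhibitors of cyclin-dependent kinases; the related Cdkn1b had a region in 3 libraries (chromosome 6, 134920301 to 134920542). Rcan1, which encodes a regulator of calcineurin, had a Meis1 region in both controls and Paro/Neo replicate 1, and Ppp3ca, the calcineurin catalytic subunit, in both controls. Meis2 likewise had a region in both controls, and Hoxb13 a peak in control replicate 2 alone. In the Hoxb13 libraries, peaks at Cdkn1a, Rcan1, Ppp3ca, Meis1 and Meis2 were called in Paro/Neo replicate 2 alone, and Cdkn2a, Cdkn2b and Hoxb13 had none in any of the 4 libraries. Hoxb13 Paro/Neo replicate 2 had a peak at 10169 of the 21883 protein-coding genes, against 920 to 5303 in the other Hoxb13 libraries. A peak at a given gene in that library is therefore common and does not single these genes out.

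Hoxb13 peaks lay at sarcomere, calcium handling and energy metabolism genes. Sarcomere genes held a region called in at least 2 Hoxb13 libraries at 17 of 26 members, against 6.29 in length-matched lists, and regions at Actc1, Myh6, Myh7 and Ldb3 were called in all 4 libraries. Calcium handling and conduction genes held 12 of 23 members against 5.80, with Pln (phospholamban), Atp2a2 (the sarcoplasmic reticulum calcium pump), Gja1 (connexin 43) and Trdn in all 4 libraries. Fatty acid oxidation genes held 17 of 22 against 5.68, with Pdk4, Fabp3 and Esrra in all 4, and oxidative phosphorylation genes 21 of 32 against 7.45, with Atp5a1, Atp5b, Cyc1 and Cs in all 4. Glycolysis and HIF genes held 14 of 24 against 5.97, among them Gapdh and Gpi1 in all 4 libraries.

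Lists beyond muscle and metabolism also passed for Hoxb13: the Hippo pathway at 14 of 18 members against 4.56 (Tead3 in all 4 libraries), cardiac transcription factors at 12 of 21 against 5.28 (Hand2 in all 4), endothelial markers at 11 of 19 against 4.50 (Fabp4 and Egfl7 in all 4), and ribosomal proteins at 22 of 41 against 8.90. The 9 passing lists had adjusted permutation p-values from 0.00067 to 0.016, and the same 9 had an unadjusted p under 0.05. The ribosomal protein list depended on 2 libraries: without Paro/Neo replicate 2 it held 1 member against 2.97 in matched lists, and without control replicate 1 it held 3 against 3.20. Other lists ceased to pass while staying above matched lists. Without Paro/Neo replicate 2, oxidative phosphorylation genes held 6 members against 2.21 and endothelial markers 3 against 1.29, and 6 lists passed. Without control replicate 1 these lists held 6 against 2.40 and 4 against 1.42, and the Hippo pathway, which also ceased to pass, 5 against 1.42. In that case 5 lists passed. Sarcomere and calcium handling genes were the 2 lists that passed with regions called in all 4 libraries. Cardiac transcription factors held 8 members against 3.555 in matched lists with peaks of −log10 q of at least 2 (adjusted permutation p = 0.0593). Calcium handling genes held 10 against 5.11 when regions counted only within 5 kb of a gene end (adjusted permutation p = 0.0607).

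**Figure D5:**
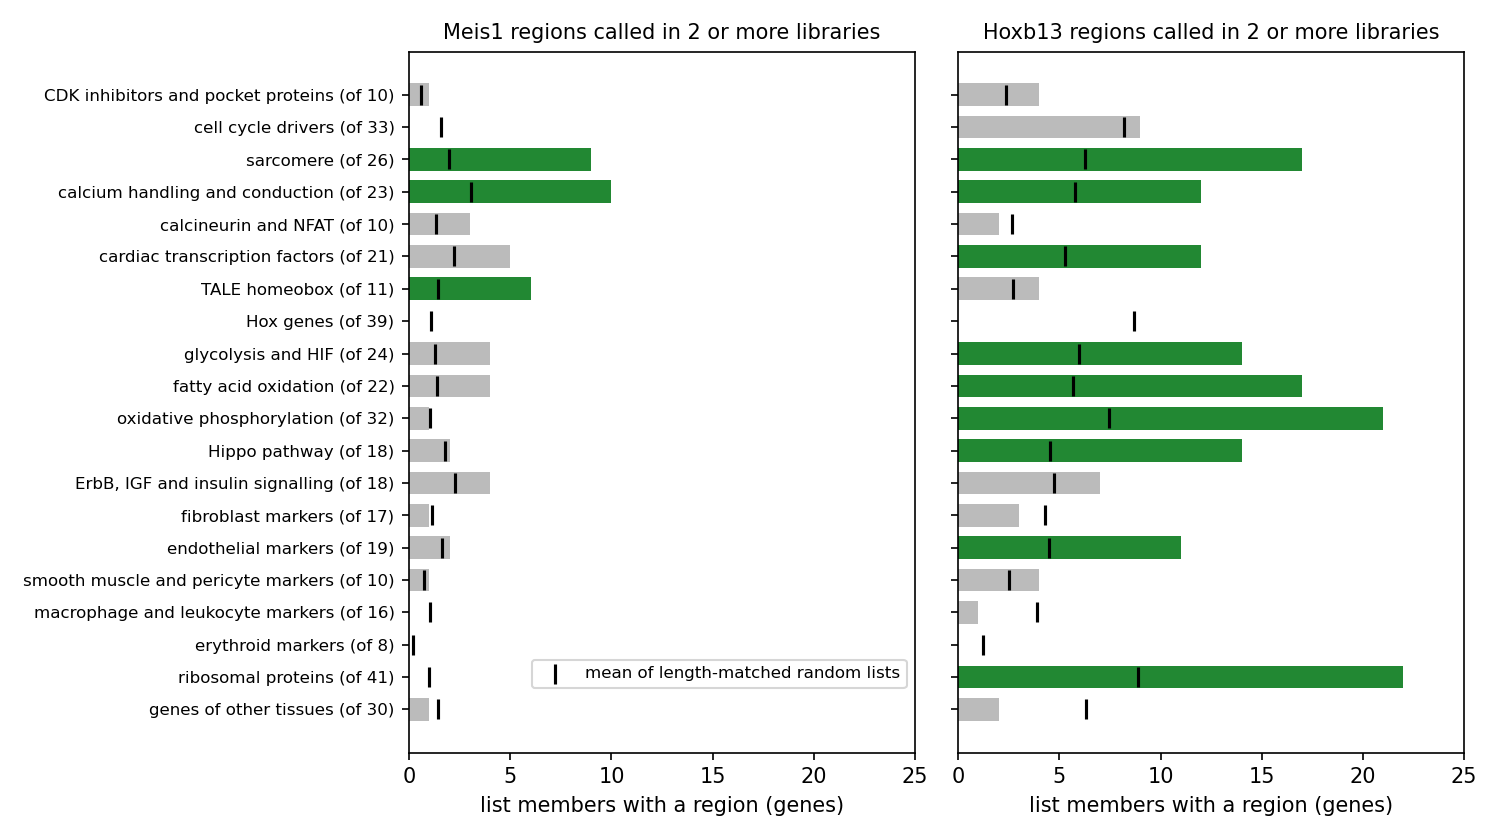
Members of each of the 20 gene lists with a region called in at least 2 Meis1 (left) or Hoxb13 (right) libraries, as bars in numbers of genes; black ticks are the mean of 10000 length-matched random lists, and green bars are lists with an adjusted permutation p under 0.05. For Meis1, 3 lists passed, and for Hoxb13, 9.

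The other Hoxb13 lists did not pass. Hox genes held 0 of 39 members against 8.71 in matched lists, genes of other tissues 2 of 30 against 6.34, macrophage and leukocyte markers 1 of 16 against 3.87, erythroid markers 0 of 8 and fibroblast markers 3 of 17. CDK inhibitors and pocket proteins held 4 of 10, with Cdkn2d in all 4 libraries, and cell cycle drivers 9 of 33 against 8.21, with Cdk2 and E2f3 in 3 libraries. TALE homeobox genes held 4 of 11, calcineurin and NFAT genes 2 of 10, ErbB, IGF and insulin signalling genes 7 of 18, and smooth muscle and pericyte markers 4 of 10.

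The treatment difference in Hoxb13 peak number was smaller than the spread between replicates. Of the 901 regions called in both controls, 449 were called in both Paro/Neo libraries, 449 in 1 and 3 in none. The long list of Paro/Neo replicate 2 alone held 88.6% and 94.1% of the peaks of control replicates 1 and 2. The 3 regions called in neither Paro/Neo library lay just outside Nr4a1 (mean fold percentile 60.1) and within Usp15 (8.10) and Sfi1 (1.17), the latter regions weak within their lists. Regions specific to the Paro/Neo libraries numbered 32 and included Zfp280d, Jup (plakoglobin), Hopx, a homeodomain regulator of heart development, Myo18b and Ndufa12; with equal list lengths, 41 regions were specific to control and 34 to Paro/Neo. Peaks numbered 8892 ± 11414 after Paro/Neo and 3162 ± 2886 in control (SD, n = 2 each). The mean log2 numbers differed by 0.63, a ratio of 1.55 (exact two-sided permutation p = 1). The mean log2 covered lengths differed by 0.78 (exact permutation p = 1). The sign depended on single libraries: the peak number difference was −1.56 without Paro/Neo replicate 2 and −0.48 without control replicate 2, and it was 1.74 without control replicate 1 and 2.81 without Paro/Neo replicate 1. Group-specific regions became 463 for control against 66 for Paro/Neo without Paro/Neo replicate 2, and 590 against 36 without control replicate 2. Without control replicate 1 they were 63 against 247, and without Paro/Neo replicate 1 they were 6 against 12572.

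Hoxb13 lists of different lengths were nested. Control replicate 1 held 87.8% of the peaks of control replicate 2, and Paro/Neo replicate 2 held 96.7% of the peaks of Paro/Neo replicate 1, while 12540 of the 17634 merged regions were called in Paro/Neo replicate 2 alone. The Jaccard share was 0.177 between the controls, 0.041 between the Paro/Neo libraries and 0.195 ± 0.126 (SD of 4 pairs) between groups. Lists of such unequal length cannot share much by this measure. With every list reduced to its strongest 821 peaks the shares were 0.372, 0.3105 and 0.363 ± 0.044 (SD of 4 pairs). Regions called in all 4 Hoxb13 libraries numbered 449, and the highest-ranked of them lay at Slc44a1 (choline transporter), Stx16, Cenpu, Foxj3, Tpcn1, Usp7 and Pln, and at 1.83 kb from Cd3e and 2.84 kb from Tle2.

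The test did not separate the treatment differences of the antibodies. Because antibody coincided with sample set, it could not have told a difference between antibodies from one between sets. The Hoxb13 difference in log2 peak number exceeded the Meis1 difference by 2.04 (exact two-sided permutation test, p = 0.389). This value was −0.14 without Hoxb13 Paro/Neo replicate 2, 0.93 without Hoxb13 control replicate 2, 3.15 without Hoxb13 control replicate 1 and 4.23 without Hoxb13 Paro/Neo replicate 1. With the second Meis1 replicates exchanged it was 0.41 (exact permutation p = 0.889).

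Meis1 and Hoxb13 shared few but more than randomly placed regions. In control hearts, 51 of the 2033 Meis1 regions called in both libraries overlapped a Hoxb13 region called in both libraries (2.51%, 95% exact interval 1.87 to 3.29), against 1.41 after random placement and 7 at most. After Paro/Neo, 29 of 651 overlapped (4.45%, 3.003 to 6.335), against 0.607 on average. Both had a one-sided permutation p = 0.001, the smallest that 1000 placements can give. In control, the 10 shared regions with the highest mean fold percentile in the Meis1 lists were named after their values were seen. Hoxb13 fold played no part in this ranking. The regions overlapped Aph1b, Ldb3, Ska2, Ssbp2 and Actn2, or lay outside Pabpn1, Phf13, Mb (myoglobin, 0.916 kb) and Dusp1 (1.41 kb), a phosphatase gene induced by stress. The rest had no protein-coding gene within 10 kb. The difference between the groups was not tested. Without the regions called in all 8 libraries the shares were 1.84% in control and 1.74% after Paro/Neo, and with equal list lengths they were 0.865% and 2.43%. At a −log10 q of at least 2 they were 1.70% and 2.78%, and at 3 they were 1.25% and 1.51%. With the second Meis1 replicates exchanged they were 3.63% and 2.96%.

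Regions called in all 8 libraries numbered 18. No list of known artefact regions was applied, so they cannot be taken as sites bound by both factors. They included Dusp1, Mb, Mib1, Lrrc10, which encodes a cardiac leucine-rich repeat protein, Ephb4, Hspb7, a cardiac small heat shock protein, and Irf2bp2. The lowest mean fold percentiles among them were 1.37 within Cdk8, 1.04 at chromosome 17, 39843016 to 39848824, and 0.884 at chromosome 9, 2999991 to 3002288, the last pair with no protein-coding gene within 10 kb.

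A higher share of peaks lay near gene ends in each of the 4 Hoxb13 libraries than in any of the 4 Meis1 libraries, a difference that was not tested. Antibody coincided with sample set, so this cannot be told apart from a difference between the sets. Within 1 kb of either end of a protein-coding gene lay 65.9%, 63.8%, 62.5% and 44.8% of the Hoxb13 peaks in control replicates 1 and 2 and Paro/Neo replicates 1 and 2, where random placement gave 4.13% to 4.28%. For Meis1 the shares were 10.5%, 11.2%, 7.79% and 10.8%, against 3.53% to 3.62%. The Paro/Neo share minus the control share was −11.2 percentage points for Hoxb13 (exact two-sided permutation p = 0.333, the smallest possible) and −1.57 points for Meis1 (exact permutation p = 0.667). Without Paro/Neo replicate 2 the Hoxb13 difference was −2.37 points, and without Paro/Neo replicate 1 it was −20.0 points; with equal list lengths it was −3.65 points (exact permutation p = 0.667). The Meis1 difference was −0.047 points without Paro/Neo replicate 1 and −3.09 without Paro/Neo replicate 2, and it was 0.93 with equal list lengths.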

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

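The alternatives of the gene lists that leave out a library, require all 4 libraries or count a region once, and the exchange of the second Meis1 replicates for peak number, covered length, gene-end share, antibody difference and overlap with Hoxb13, were chosen after seeing the data; the others were planned. Differences are Paro/Neo minus control. The Meis1 peak number (−1.12 to −1.71, log2) and covered length (−1.13 to −1.70) kept their sign with each library left out and under every planned setting, but 2 against 2 libraries cannot pass the threshold, so this says nothing about significance. With the second Meis1 replicates exchanged both reversed, to 0.2181 and 0.2189. Leaving out libraries moved Hoxb13 peak number from −1.56 to 2.81, covered length from −1.48 to 3.04, the antibody difference from −0.14 to 4.23, the log2 ratio of group-specific regions from −6.23 to −1.88 for Meis1 and from −4.02 to 10.9 for Hoxb13, and passing Hoxb13 lists from 5 to 9. The log2 ratio for Meis1 (main −5.70) was −6.43 and −7.43 at −log10 q of at least 2 and 3, and that for Hoxb13 (main 3.22) was 2.48 at 3. With equal list lengths the Meis1 ratio was −1.09, the Hoxb13 ratio −0.27, the Meis1 replicate overlap difference 0.001128 and the Meis1 gene-end difference 0.93 points; lists of unequal length give the longer pair more regions of its own by construction. Exchanging the second replicates gave ratios of 1.26 and −12.7 and overlap differences of −0.059 and 0.193 for Meis1 and Hoxb13; splitting by replicate number gave ratios of −1.66 and 6.74 and a Meis1 overlap difference of −0.055. With regions called in all 4 libraries, 1 Meis1 and 2 Hoxb13 lists passed, and ribosomal proteins held 0 members against 1.42 matched; with a library left out they held from 1 (without Paro/Neo replicate 2) to 22, with 3 without control replicate 1. The cause was not tested for the other changes. The Meis1-Hoxb13 overlap passed under every planned setting. The labels do not say that replicate numbers mark a shared litter or day, and deviations of same-numbered libraries correlated across regions at −0.0028 for Meis1 and 0.204 for Hoxb13. As a replicate block, the differences were −1.41 and 0.63 in log2 peak number, −1.41 and 0.78 in covered length, −1.57 and −11.2 points in gene-end share and 2.04 between antibodies, with exact sign-flip p-values of 0.5 or 1; 2 pairs cannot give a p under 0.5, so the block could change no call. The pairs of Hoxb13 differed by −2.66 and 3.92 in log2 peak number. Planned motif alternatives were not run. Unknown depth limits every statement that a peak was absent.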

Other observations

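The tests of the Meis1 peak number, the Hoxb13 replicates and the ribosomal protein list below were chosen after the results were seen; the test of the metabolism genes was written before it was run. The choice of the widest regions was also made after their values were seen.

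Single Hoxb13 peaks reached 96161 bp in Paro/Neo replicate 2, against 25845 bp and 17827 bp in control replicates 1 and 2 and 18084 bp in Paro/Neo replicate 1, so the largest widths rest on 1 library. Of the 15 widest merged regions called in 2 or more Hoxb13 libraries, the widest, 96161 bp, lay over part of Ttn (chromosome 2, 76699718 to 76795878), which held 3 more. Others overlapped Fhl2 (71151 bp), the calcium pump gene Atp2a2 (54022 bp, chromosome 5, 122449018 to 122503039), Myh6 and the end of Myh7 (40787 bp), Myh7 (30478 bp), Tnnt2 (21265 bp), Dapk3 (19596 bp), Fam181a (18526 bp), the thin filament gene Lmod2 (16110 bp) and Ryr2 (15890 bp). The remaining ones lay outside Frmd8 (23013 bp) and with no protein-coding gene within 10 kb (21078 bp). Whether any gene group was over-represented among these regions was not tested. Peaks of at least 5 kb numbered 34 and 13 in the Hoxb13 control libraries and 15 and 121 in the Paro/Neo libraries, and 1 in each Meis1 library. The wide Meis1 region called in 2 or more libraries (chromosome 17, 39843017 to 39848821) lay in a region called in all 8 libraries, with no protein-coding gene within 10 kb.

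Fewer Meis1 peaks after Paro/Neo may reflect lower enrichment that removes the weakest calls first, which cannot be told apart here. With equally long lists, replicates exceeded pairs of different groups by 0.001128 in mean Jaccard share, but this mean decides nothing. The controls (0.512) lay above and the Paro/Neo pair (0.390) below the between-group mean of 0.450, each by more than its SD of 0.0478. The low shares were those of pairs with Paro/Neo replicate 2 (0.390 to 0.410), against 0.480 to 0.512 for the other pairs. Lower sequencing depth cannot be told apart either, because the caller's scaling is unknown; the background back-calculated from fold and p, under an assumed formula of the caller, was 0.899 times that of the controls, while peak number was 0.375 times. Exchanged labels of the second replicates also stay open, since the 0.005302 by which the exchanged grouping differed from the labels' at equal list lengths rests in both groupings on 2 pairs lying on opposite sides of the between-group mean and could not separate them. An effect of the drugs on Meis1 binding remains open and untested by these values.

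Regions at energy metabolism genes were hypothesised to be lost after Paro/Neo beyond what their fold in the controls gives. Of 9 regions of both controls at glycolysis, fatty acid oxidation and oxidative phosphorylation genes, 7 were absent from both Paro/Neo libraries, against 4.22 expected from regions of the same fold quartile. The one-sided permutation p was 0.05149, which missed the 0.05 threshold set beforehand by less than its own simulation error of 0.0022, so the hypothesis was not supported and, with 9 regions, cannot be told apart from chance. Without the quartiles, which were the point of the test, Fisher's exact p was 0.0341 (chosen afterwards).

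Peak numbers of Hoxb13 replicates moved in opposite directions, with control replicate 1 holding 4.64 times the peaks of replicate 2 and Paro/Neo replicate 2 holding 20.7 times those of replicate 1. If the same sites had only been called further down a shared ranking, equally long lists were predicted to overlap alike. Of the 3 ways to split the libraries into pairs, that of control replicate 1 with Paro/Neo replicate 2 exceeded its between-pair mean by 0.0596 in Jaccard share. This was above the SD of 0.0305, so the prediction failed. The excess came mostly from this pair (0.415), since the other pair (0.375) hardly exceeded the controls (0.372). However, the top 821 peaks are the strongest part of the long lists but all or most of the short ones. The long lists could therefore overlap more even under a shared ranking, so the failed prediction cannot decide against that explanation. The shorter list held 57.7% of the top 821 peaks of the longer list against 18.3% of all its peaks in control. After Paro/Neo the shares were 45.8% and 4.13%. A short list can hold only a small part of a far longer one, so this contrast gives no evidence for a shared ranking. An identical ranking would place nearly all of the top peaks in the shorter list, which was not seen. A looser shared ranking is neither supported nor excluded by these values. Different depth stays open and cannot be told apart, since the back-calculated background of the longer list was 0.872 times that of the shorter in control and 0.913 times after Paro/Neo, but on a scale that is unknown. No biological explanation was tested, as the replicates belong to the same groups.

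Hoxb13 regions at metabolic, contractile and ribosomal protein genes may come from recovery of highly transcribed chromatin whatever the factor. The ribosomal protein genes, transcribed in every cell, held more regions than matched lists (adjusted permutation p = 0.00067), as this explanation needs. That excess was absent without Paro/Neo replicate 2 (1 member against 2.97 in matched lists) or without control replicate 1 (3 against 3.20). Oxidative phosphorylation genes then no longer passed but stayed above matched lists, at 6 members against 2.21 and 2.40. Sarcomere, calcium handling, fatty acid oxidation and glycolysis genes still passed, so the explanation cannot be told apart from binding of Hoxb13 in the other libraries. A direct test would need libraries from hearts without Hoxb13, which are not analysed here.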
